A study of Mus musculus with 4 samples.

How the data were processed

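The data are RNA sequencing libraries from mouse heart, 2 from Sham and 2 from MI hearts at day 28. Per the labels' protocols, poly(A) RNA was selected from total RNA, fragmented and made into strand-marked (dUTP) paired-end libraries. The deposited table gives each gene's Ensembl identifier, symbol, position, annotation terms and, for each library, an estimated count and an FPKM, a fragment abundance scaled for gene length and library size. The estimated counts are whole numbers, and the deposited FPKM values were normalized by the authors for gene length and library size, per the file headers. The tools named are cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and UMI-tools (version not given), per the submitters' processing notes, which give no role or order. Whether molecular identifiers were used in the counting, whether strand was, and the genome build are not given in the sources used here. Of the 55401 gene identifiers, 99.5% occur in the GRCm38 annotation (GENCODE M21), and 94.2% have the same start and end there.

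The estimated counts are not 1 per fragment. Low values pile up at multiples of 4: in Sham replicate 1, 1158 genes have a count of 4 and 284 a count of 3, with 1167 and 311, 1174 and 331, and 1148 and 290 in the other libraries. A count of 12 therefore stands for about 3 fragments and was used as the floor per library. A floor or interval covers counting error only, since fragments copied by PCR are not independent molecules. No column lacked a labelled sample, and no gene lacked a name.

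The groups were taken from the sample titles. Nothing states that the replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical. With 2 libraries per group an exact permutation test cannot give a 2-sided p under 0.33, so all tests rest on models that pool the spread over genes. The gene lists, the rule for named genes, the design and most alternatives were fixed before the data were examined. The design foresaw limma on log2(FPKM + 1) unless the table held counts; it does, so edgeR became the main test, as the design provided, and limma an alternative.

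Genes were filtered with filterByExpr (min.count 10, min.total.count 15), which left 18475, scaled by TMM (factors 0.877, 0.975, 1.15 and 1.02 in the order Sham 1, Sham 2, MI 1, MI 2) and tested with edgeR 4.0.16 (R 4.3.3), by a 2-sided quasi-likelihood test with group as the only term and Benjamini-Hochberg adjustment at 0.05. Because no gene passed, the count at an unadjusted p under 0.05 is reported too. CPM are TMM-scaled and calculated from the estimated counts. The standard error of a log2 difference comes from the fitted model. The biological coefficient of variation was 0.368. The Pearson correlation of log CPM across genes was 0.934 between the Sham libraries, 0.961 between the MI libraries and 0.936 to 0.946 between groups.

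In all, 48 gene lists were fixed, covering matrix, fibroblasts, cardiomyocytes, metabolism, immune cells, redox, stress responses and other cell types or tissues. Lists with at least 5 tested members (46) were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists. The alternatives were camera with an estimated correlation and fry, which asks whether the members move on balance in 1 direction and does not compare them with other genes. For each list the number of members passing an adjusted p under 0.05 over the list alone is given. That adjustment does not cover the 46 lists or the other genes, so a member that passes it is not a gene called. Lists overlap, for example in Tbx5, Thbs4 and Fbln1, so they are not independent. Annotation terms of the table with 15 to 300 tested genes (2688) were tested in the same way. A list described as called has an adjusted p under 0.05 with the preset correlation.

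The rule for named genes was: with no gene called, the 10 with the smallest p; 16 genes fixed by name (Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1, Postn, Fn1, Timp1, Spp1, Tgfb1, Acta2, Cpt1b and Ppargc1a); for each list described, up to 2 members of highest mean FPKM; and the sex-linked and contamination check genes. One gene named by this rule is not reported here. Any other gene is said to have been chosen after its values were seen. Spp1, osteopontin, had 42.1 and 0.94 CPM in the Sham libraries and 9.34 and 3.48 in the MI libraries.

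The steps were tested on simulated counts drawn from the means and sizes of the libraries, with 200 of 17760 genes changed. Of 100 genes changed by 2 on the log2 scale 74% were called, and of 100 changed by 4, 96%. Among unchanged genes, 4.57% had an unadjusted p under 0.05 and 8 were called. The draw gave no library a shift shared by many genes, so these shares need not hold in the real libraries. There Thbs4, with a log2 difference of 4.305, had an adjusted p of 0.185 in edgeR. A shifted set had a camera p of 7.52e-21 and of 0.00942 with an estimated correlation, and an unchanged set 0.94. Each gene was drawn independently, so the simulation cannot check the preset correlation on sets whose members move together. In the real libraries the estimated correlation of the lists ran from -0.0407 to 0.97. It was 0.52 for the collagens and 0.709 for the fatty acid genes.

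The alternatives were median-of-ratios scaling, removal of mitochondrial transcripts with scaling to the remaining total, quantile normalization, pseudocounts of 0.1 and 0.5 on FPKM, no filter, a mean FPKM of at least 5, limma without a variance trend, robust empirical Bayes, summing genes that share a symbol, the replicate number as a block, other thresholds (a 2-fold change, or an unadjusted p), and leaving out each library. Alternatives added after seeing the data were DESeq2 1.42.0, limma on log2(FPKM + 1) in its place as an alternative, counts divided by 4, a newer quasi-likelihood fit, and a mean FPKM of at least 1. When a library is left out, the lone library of that group is assumed to vary like those of the other group.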

Results

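Poly(A) RNA from mouse hearts was sequenced 28 days after surgery. The Sham group (n = 2) had the chest opened without ligation, and the MI group (n = 2) had the ligation operation that produces a myocardial infarction, the death of heart muscle after its blood supply is stopped. The design text speaks of infarcted tissue against normal left ventricle, whereas the samples are labelled only as heart, so the region taken is not known per sample. The series title names cyanidin, a plant pigment. Cyanidin-treated hearts were not analysed here. The single comparison asks which transcripts differ between infarcted and Sham hearts at day 28. Total estimated counts were 72485370 and 66624106 in Sham replicates 1 and 2, and 72857907 and 75979320 in MI replicates 1 and 2, at an apparent 4 counts per fragment. Transcripts encoded in mitochondrial DNA took 34.0% and 32.6% of the counts in the Sham libraries and 27.3% and 30.9% in the MI libraries. The 10 most abundant genes took 36.8%, 34.9%, 29.8% and 33.5%, in the same order.

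The infarcted hearts held more transcript for matrix proteins and less for mitochondrial and ion channel proteins, in tests of gene groups with a preset correlation. With an estimated correlation 0 of these groups were called. Gene by gene, of 18475 genes tested, 0 passed an adjusted p under 0.05 in edgeR's quasi-likelihood test (smallest adjusted p = 0.185). At an unadjusted p under 0.05 there were 2150 genes, 1316 higher and 834 lower in MI, where chance alone would give 924. DESeq2 called 635 genes, 403 higher and 232 lower, and limma on log2(FPKM + 1) called 0. Counts over a list alone and at an unadjusted p under 0.05 below are edgeR's, and those of DESeq2 are over all genes tested. Both MI libraries lay above both Sham libraries for 4594 genes and below both for 4039, together 46.7% of the genes, where chance gives 33.3%. The share of higher genes among those at an unadjusted p under 0.05 was 61.2% with trimmed-mean (TMM) scaling, 82.0% with mitochondrial transcripts removed and the rest scaled to its total, 88.6% in limma on FPKM and 56.2% after quantile normalization. Relative to TMM, the median of all genes moved up by 0.14 on the log2 scale without the mitochondrial transcripts, and by 0.15 to 0.19 on the FPKM scale. Fits with a Sham library left out largely followed the Sham library that remained. Without Sham replicate 1, each gene called lower in MI had its highest count in Sham replicate 2. Examples were Myl4, Bmp10 and Adipoq, with 62376, 18757 and 1602 counts there against 151, 0 and 0 in Sham replicate 1. Of those called higher, Alb and Spry1 had 0 and 24 counts in Sham replicate 2, while Cilp was higher in both MI libraries. With 0, 8 and 3982 counts in Sham replicate 1, Eif3j2, Adnp and Gm20716 were among the genes called without Sham replicate 2. Without MI replicate 1 or 2 there were 0.

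The 10 genes with the smallest p-values are given as values that did not pass, each with an adjusted p of 0.185 in edgeR. Thbs4, a matricellular thrombospondin (ENSMUSG00000021702, chromosome 13, 92751590 to 92794818, GRCm38), averaged 4.18 ± 0.58 CPM (counts scaled for library size; SD, n = 2) in Sham and 82.8 ± 23.7 in MI, a log2 difference of 4.30 ± 0.28 (SE). Col12a1, a fibril-associated collagen (ENSMUSG00000032332, chromosome 9, 79598991 to 79718720), averaged 1.39 ± 0.12 CPM in Sham and 22.5 ± 6.65 in MI (log2 difference 4.01 ± 0.29). The secreted angiopoietin-like gene Angptl7 averaged 5.56 ± 1.9 CPM in Sham and 92.9 ± 18.2 in MI. Cilp, a cartilage matrix protein, had 7.30 and 12.7 CPM in the Sham libraries and 136 and 140 in the MI libraries. Mfap5, a microfibril protein, had a log2 difference of 2.17 ± 0.18. Pmp22, a peripheral myelin protein, had 1.96 ± 0.15, and Rap1gap2, an activator of Rap GTP hydrolysis, 1.55 ± 0.14. Agt, the angiotensin precursor (ENSMUSG00000031980, chromosome 8, 124556534 to 124569706), went the other way, from 57.1 ± 1.08 CPM in Sham to 5.62 ± 2.02 in MI (log2 difference -3.34 ± 0.29). The antisense gene Atcayos averaged 93.8 ± 12.2 CPM in Sham and 21.5 ± 3.53 in MI. Its value is uncertain, since whether the counting used strand is not stated. Gm21451 (chromosome 14, 69390854 to 69480287) had no counts in either Sham library and 6.83 ± 1.76 CPM in MI. That is at least 36.6-fold higher against a floor of 12 counts per Sham library. Its gene type is not given here, and reads shared with a similar gene were not checked, so its value is uncertain.

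**Figure D1:**
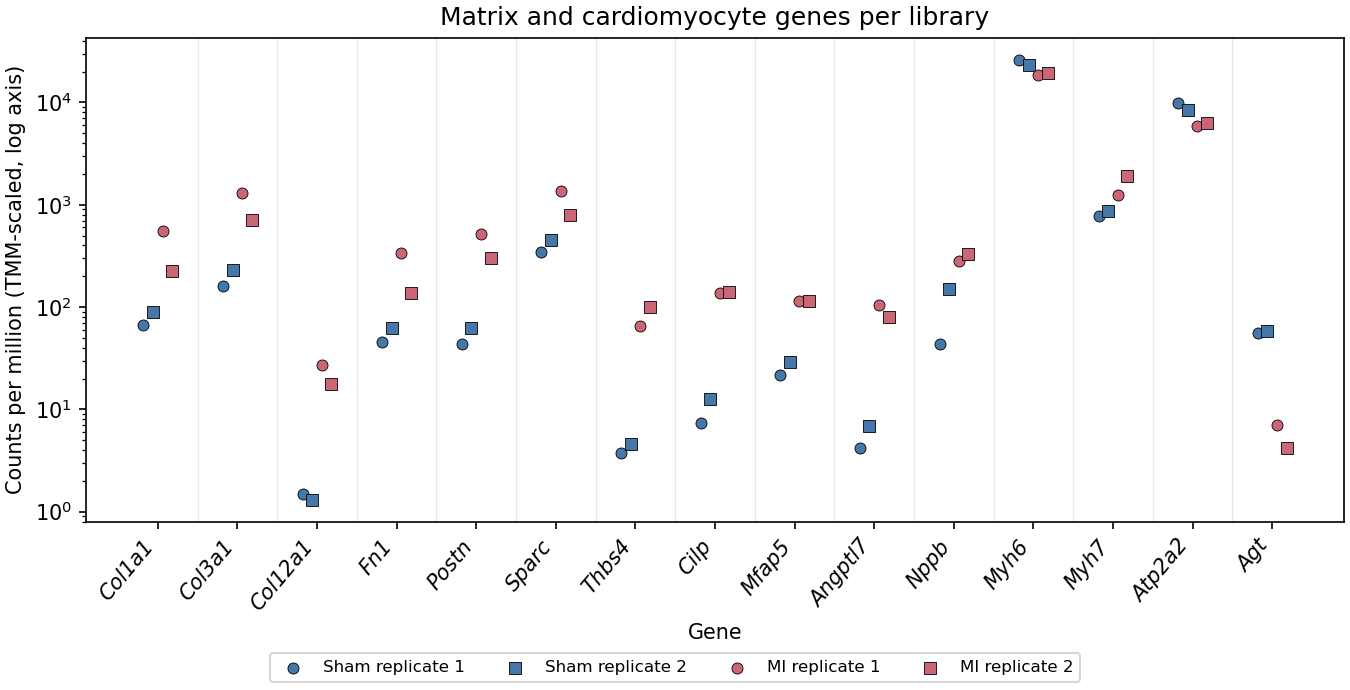
TMM-scaled CPM (log axis) of 15 matrix, cardiomyocyte and signalling genes in each library, with blue for Sham, red for MI, circles for replicate 1 and squares for replicate 2. Both MI points lie above both Sham points for Col1a1 through Angptl7, Nppb and Myh7, and below them for Myh6, Atp2a2 and Agt. None of these genes passed the adjustment over all genes in edgeR.

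Collagens and other matrix genes were higher in MI. Of 18 fibrillar and associated collagens, 17 were higher when adjusted over the list alone and at an unadjusted p, against 0 over all genes tested in edgeR and 16 in DESeq2. The median log2 difference was 2.14. Col1a1, a chain of type I collagen, averaged 77.9 ± 15.5 CPM in Sham (n = 2) and 388 ± 231 in MI (log2 difference 2.32 ± 0.47). Col3a1, type III collagen, averaged 197 ± 49.5 and 1004 ± 428 CPM. Among collagens chosen after their values were seen, Col11a1, Col8a2 and Col22a1 had log2 differences of 4.93 ± 0.89, 4.42 ± 0.66 and 3.87 ± 0.38. In the Sham libraries Col11a1 had 4 and 21 counts, Col8a2 15 and 52, and Col22a1 22 and 22. These lie near the floor of 12, so the size of the differences is uncertain. Of 32 non-collagen matrix and matricellular genes, 21 were higher adjusted over the list alone and 0 lower (22 and 0 at an unadjusted p, 20 and 0 in DESeq2), with a median of 1.47. Postn, which encodes periostin, averaged 52.9 ± 13.8 CPM in Sham and 413 ± 153 in MI, and Fn1, fibronectin, had 54.0 ± 11.6 and 237 ± 144. Sparc, the most abundant member, had a log2 difference of 1.44 ± 0.32, while the injury-responsive Ccn2 had 0.25 ± 0.64. Eln (elastin), chosen after its value was seen, had 2.68 ± 0.42. Both lists were called higher by camera with a preset correlation (adjusted p = 4.34e-39 and 2.04e-32). Neither was with an estimated correlation (adjusted p = 0.531 for both). MI replicate 1, which carried lung transcripts, had the higher level of most of these genes (Col1a1 at 551 against 225 CPM in MI replicate 2). Without it, 12 collagens and 8 other matrix genes were higher adjusted over the list alone, with list medians of 1.58 and 1.05. The median of the other matrix genes was 2.24 without Sham replicate 2.

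The enzymes that modify and crosslink collagen were higher in MI, with 10 of 21 higher adjusted over the list alone and a median log2 difference of 0.86. Serpinh1, the collagen chaperone, had 1.15 ± 0.54 and the transglutaminase Tgm2 0.28 ± 0.17. Loxl3, Lox and P4ha1, chosen after their values were seen, had 2.31 ± 0.31, 1.55 ± 0.43 and 0.86 ± 0.14. The list was called by camera (adjusted p = 3.05e-13; adjusted p = 0.603 with an estimated correlation). Without MI replicate 1 and MI replicate 2 the members higher over the list alone numbered 1 and 4. Of 22 activated fibroblast and myofibroblast markers, 10 were higher adjusted over the list alone (16 without Sham replicate 2), with a median of 1.44 (camera adjusted p = 4.42e-24; adjusted p = 0.531 with an estimated correlation; median 2.55 without Sham replicate 2). Acta2, the smooth muscle actin of myofibroblasts, was not among them, at 0.13 ± 0.38. It was -0.20 without Sham replicate 1 and -0.34 without MI replicate 1. Cthrc1, Sfrp2, Ltbp2 and Aspn, chosen after their values were seen, had 5.35 ± 1.48, 4.25 ± 0.73, 4.17 ± 0.40 and 2.15 ± 0.21. Cthrc1 had 45 and 0 counts in the Sham libraries, so the size of its difference is uncertain. Resting fibroblast markers had a median of 0.43, and 5 of 20 were higher adjusted over the list alone. These were Pi16, Pdgfrl, Lamc1, Fbln1 and Ogn, named after their values were seen. The abundant Gsn and Ly6a had 0.02 ± 0.25 and 0.73 ± 0.31. That list was called (adjusted p = 0.0012; adjusted p = 0.603 with an estimated correlation), but not without Sham replicate 1 (adjusted p = 0.0759). The members higher over the list alone numbered 2, 8, 0 and 2 without Sham replicates 1 and 2 and MI replicates 1 and 2. The lower members numbered 1, 2, 0 and 0, and the median was 0.69 without Sham replicate 2. The activated and resting fibroblast medians were 2.14 and 0.63 in limma on log2(FPKM + 1), and 2.33 and 0.67 with a pseudocount of 0.1.

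Genes of the TGF-beta pathway, a main profibrotic signal, had a median log2 difference of 0.27, with 6 of 28 higher and 1 lower adjusted over the list alone. Tgfb1 averaged 18.3 ± 0.82 CPM in Sham (n = 2) and 28.7 ± 1.12 in MI (log2 difference 0.64 ± 0.14). The latent TGF-beta binding protein Ltbp4 had 0.79 ± 0.28 and Fstl1 1.77 ± 0.33. Tgfb3 (1.58 ± 0.27) and the lower Inhbb (-1.33 ± 0.30) were chosen after their values were seen. Matrix proteases and their inhibitors had a median of 0.32, with 2 of 29 higher (Mmp2, 1.61 ± 0.21, and Adam19, 1.09 ± 0.21) and 1 lower (Adamts4, -2.21 ± 0.34) adjusted over the list alone, all named after their values were seen. The cathepsins Ctsd and Ctsb differed by 0.07 ± 0.16 and 0.04 ± 0.18, and the inhibitor Timp1 by -0.36 ± 0.71 (1.15 without Sham replicate 1). Camera called both lists higher (adjusted p = 0.00537 and 0.0392), with an adjusted p of 0.603 for each with an estimated correlation. The TGF-beta call ended without Sham replicate 1 (adjusted p = 0.209) or MI replicate 1 (0.299). Without either MI library 1 of its members passed over the list alone. The protease call ended without Sham replicate 2 (0.295), MI replicate 1 (0.377) or the mitochondrial transcripts (0.0839), and 0 of its members passed over the list alone without either MI library. There were 5 higher and 2 lower without Sham replicate 1, and 5 higher and 4 lower without Sham replicate 2. The protease median was 0.67 without Sham replicate 1 and 0.10 without MI replicate 1. The TGF-beta and protease medians were 0.37 and 0.56 in limma on log2(FPKM + 1), and 0.50 and 0.64 with a pseudocount of 0.1.

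**Figure D2:**
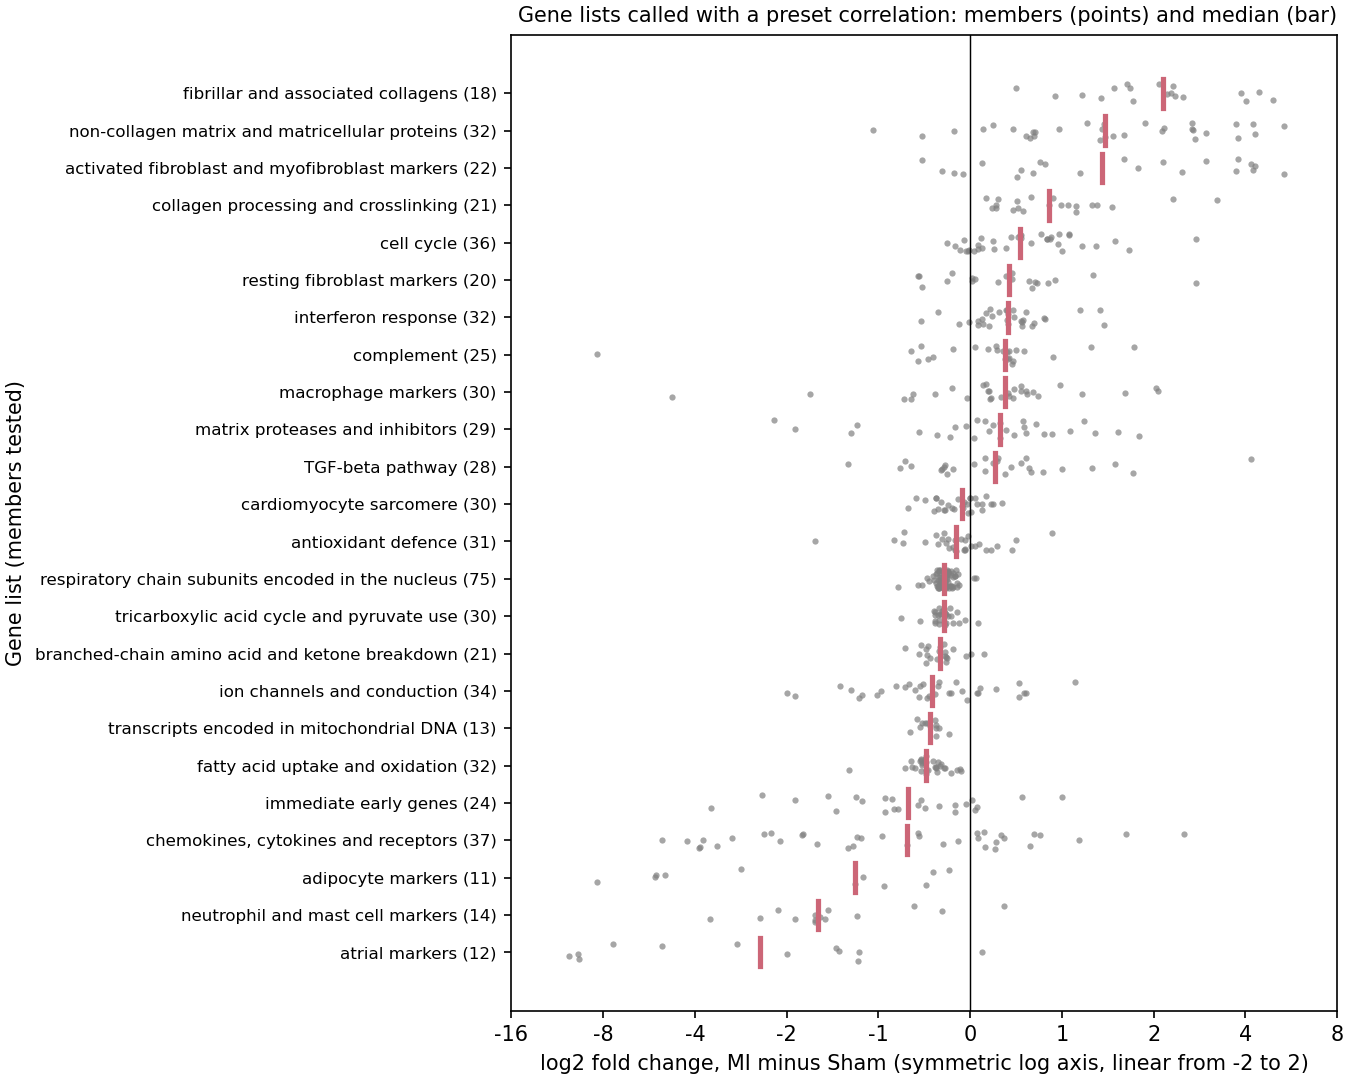
Log2 difference between MI and Sham of each tested member (grey points, symmetric log axis) and the list median (red bar) for the 24 lists called by camera with a preset correlation. The 11 lists called higher have medians from 0.27 to 2.14 and the 13 called lower from -0.08 to -2.45. Members with no counts in a group are not drawn, and 0 lists were called with an estimated correlation.

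Ion channel and conduction genes were lower in MI, with a median log2 difference of -0.41. Adjusted over the list alone, 6 of 34 were lower (6 in DESeq2; 1 higher and 12 lower without Sham replicate 1, and 2 higher and 6 lower without Sham replicate 2). The median was -0.28 without mitochondrial transcripts and -0.11 in limma on FPKM. Popdc2, a cyclic AMP binding protein of cardiac pacing, had -0.60 ± 0.13. The others, named after their values were seen, were Tbx5, Kcnj5, Scn4b, Kcnd3 and Kcnh2, at -1.21 ± 0.16, -0.97 ± 0.13, -1.42 ± 0.22, -1.18 ± 0.19 and -0.81 ± 0.14. The potassium channel Kcnk3 had -0.35 ± 0.13. Camera called the list (adjusted p = 2.98e-05; adjusted p = 0.531 with an estimated correlation), including without any single library. With a mean FPKM of at least 5 the call ended (adjusted p = 0.377). Without either MI library 0 members passed over the list alone. Tbx5 and Kcnj3 also stand in the atrial list, and atrial transcripts were abundant in Sham replicate 2. Kcnj3 was at 5.2 FPKM there, 0.87 in Sham replicate 1, and 0.89 and 0.81 in the MI libraries. Sarcomere genes differed little, with a median of -0.08 and 0 of 30 passing over the list alone in edgeR (2 lower at an unadjusted p, and 1 lower in DESeq2). Actc1, cardiac actin, had -0.08 ± 0.16 and Myh6, the main adult myosin heavy chain of the mouse ventricle, -0.37 ± 0.18. Their camera call (adjusted p = 0.0393; adjusted p = 0.701 with an estimated correlation) ended without Sham replicate 1 (0.0957), Sham replicate 2 (0.0581) or MI replicate 1 (0.555). The median was -0.16 without Sham replicate 2, -0.19 without MI replicate 2, 0.06 without mitochondrial transcripts and 0.12 in limma on FPKM.

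Fetal and stress genes of the ventricle went both ways and were not called as a list (adjusted p = 0.451), although 5 of 19 were higher and 1 lower adjusted over the list alone. The median (-0.05) and mean (-0.71) were negative while the test pointed higher. Myh7, the slow myosin heavy chain, averaged 825 ± 70.2 CPM in Sham and 1581 ± 469 in MI (log2 difference 0.94 ± 0.25). Uchl1, Xirp2, Gdf15 and Enah (1.18 ± 0.16, 0.81 ± 0.17, 3.75 ± 0.82 and 0.49 ± 0.13) and the lower Ankrd2 (-2.38 ± 0.51) were chosen after their values were seen. Without either MI library 0 of them passed, and without Sham replicate 1 there were 3 higher and 2 lower. The list was called higher without Sham replicate 2 (adjusted p = 0.0243, median 0.48). Nppb, brain natriuretic peptide, had 43.2 and 151 CPM in the Sham libraries and 281 and 328 in the MI libraries. Nppa, atrial natriuretic peptide, had 162 and 3396 CPM in Sham and 2174 and 1717 in MI. Its log2 difference of 0.13 ± 1.24 became 3.58 without Sham replicate 2, the library with atrial transcripts, and -0.80 without Sham replicate 1. Acta1, skeletal actin, had 0.37 ± 0.69, and was -0.76 without MI replicate 1 and -0.11 without Sham replicate 1. Calcium handling genes were not called (adjusted p = 0.206). The calcium pump gene Atp2a2 had -0.58 ± 0.17, and Cacna2d1, named after its value was seen, was the 1 member higher adjusted over the list alone (1.37 ± 0.18; 0 without either MI library, and 1 higher and 2 lower without Sham replicate 1).

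Genes of mitochondrial energy metabolism were lower in MI by small amounts that ran in the same direction. All 32 fatty acid uptake and oxidation genes had negative differences (median -0.48), and both MI libraries lay below both Sham libraries for 26 of them. Fabp3, the fatty acid binding protein of heart muscle, averaged 3872 ± 832 CPM in Sham (n = 2) and 2778 ± 363 in MI. Acadl differed by -0.36 ± 0.16 and Cpt1b, which admits long-chain fatty acids to mitochondria, by -0.33 ± 0.16. The tricarboxylic acid cycle list had a median of -0.28 with 29 of 30 members negative (Idh2, -0.12 ± 0.21, and 0.13 without MI replicate 1). Nuclear-encoded respiratory chain subunits had a median of -0.28 with 73 of 75 negative (Cox6a2, -0.31 ± 0.18; Atp5a1, -0.30 ± 0.16). Branched-chain amino acid and ketone breakdown had -0.33 with 19 of 21 negative (Oxct1, -0.27 ± 0.18; Acat1, -0.46 ± 0.16). All 13 transcripts encoded in mitochondrial DNA were negative (median -0.44; mt-Co1, -0.34 ± 0.25; mt-Cytb, -0.37 ± 0.21). Camera called the 5 lists lower, with adjusted p of 1.85e-10, 2.14e-05, 1.39e-09, 2.17e-05 and 2.14e-05 in the order given. Each had an adjusted p of 0.603 with an estimated correlation. In edgeR 0 members passed over the list alone (6 fatty acid genes, all lower, without Sham replicate 2). At an unadjusted p 15, 3, 7, 8 and 5 members were lower, and DESeq2 called 5, 0, 1, 0 and 2 lower. In limma on FPKM the medians were -0.24, -0.06, -0.06, -0.10 and -0.23, and without mitochondrial transcripts those of the first 4 were -0.34, -0.15, -0.14 and -0.19. Without Sham replicate 1 the fatty acid and respiratory chain medians were -0.31 and -0.18, and without MI replicate 1 the mitochondrial DNA median was -0.26. The first 4 lists were called under each of 20 settings. Mitochondrial copies on chromosome 1 took 11.2% and 10.6% of the counts in the Sham libraries and 9.26% and 10.2% in the MI libraries. The setting without mitochondrial transcripts did not remove these copies, so they stay in its total. Reads can be shared between these copies and the mitochondrial genes, so both values are uncertain. Glycolysis genes (adjusted p = 0.215) and energy regulators (0.18) were not called. Ppargc1a, a coactivator of mitochondrial biogenesis, had -0.67 ± 0.33.

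Chemokines, cytokines and their receptors were lower in MI than in Sham, with a median log2 difference of -0.69 and 9 of 37 lower and 2 higher adjusted over the list alone (10 and 2 in DESeq2). The median was -0.35 in limma on log2(FPKM + 1). Among those chosen after their values were seen, the inflammatory mediators Il6, Cxcl2, Ccl2 and Cxcl1 had -5.12 ± 1.37, -4.25 ± 0.68, -3.87 ± 0.64 and -3.03 ± 0.51. In MI replicates 1 and 2, Il6 had 17 and 0 counts and Cxcl2 had 17 and 8. These counts lie near or below the floor, so the size of the Il6 and Cxcl2 differences is uncertain. Ccl2 had 18.9 and 5.84 CPM in the Sham libraries and 0.791 and 0.89 in the MI libraries. The 2 higher members were Ccl21a, a lymphatic chemokine (1.19 ± 0.15), and Cxcr4 (1.70 ± 0.32), the latter chosen after its value was seen. The abundant Ccl6 had -0.56 ± 0.75 (1.07 without Sham replicate 1). Neutrophil and mast cell markers had a median of -1.66 with 0 of 14 passing over the list alone in edgeR (2 lower at an unadjusted p, 1 lower in DESeq2, and 6 lower over the list alone without Sham replicate 2). S100a9 had 24.5 and 4.14 CPM in Sham and 6.01 and 3.21 in MI. Lcn2 had a log2 difference of -2.44 ± 0.68. Camera called both lists lower (adjusted p = 1.01e-04 and 2.75e-04; adjusted p = 0.603 for each with an estimated correlation). Sham replicate 1 held the highest level of 13 of 18 neutrophil and mast cell markers. Without it neither list was called (adjusted p = 0.0994 for chemokines and 0.256 for neutrophils, with a median of -0.07). The chemokine call also ended without MI replicate 2 (0.0552), after quantile normalization (0.0868) and with a mean FPKM of at least 5 (0.377). Without either MI library 0 of its members passed over the list alone, and without Sham replicate 1 there were 9 higher and 10 lower. The chemokine median was -0.42 without Sham replicate 1 and -1.14 without MI replicate 1.

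Other immune lists were slightly higher in MI, and each of these calls ended without MI replicate 1. Interferon response genes had a median of 0.41 (camera adjusted p = 4.05e-04), with 2 of 32 higher adjusted over the list alone. These were Cmpk2 and Rsad2 (1.42 ± 0.19 and 1.20 ± 0.16, named after their values were seen). The abundant Ifi27l2a and Bst2 had -0.35 ± 0.40 and 0.56 ± 0.36. Macrophage markers had a median of 0.38 (adjusted p = 0.0393) with 0 of 30 passing over the list alone in edgeR (1 higher without Sham replicate 1, and 1 higher and 1 lower without Sham replicate 2). At an unadjusted p 2 were higher and 1 lower, and DESeq2 called 0. Lyz2, lysozyme, had 0.68 ± 0.32 and Apoe 0.23 ± 0.18. Complement genes had a median of 0.38 (adjusted p = 0.0393), also with C6, which had no Sham counts, at its bound. Of 25, 1 was higher adjusted over the list alone, C1s1 (1.79 ± 0.20, named after its value was seen), and C1qb and C1qa had 0.46 ± 0.24 and 0.42 ± 0.23. With an estimated correlation the adjusted p was 0.603, 0.77 and 0.677 for these 3 lists. Without MI replicate 1, which carried lung transcripts, it was 0.121, 0.798 and 0.67 with the preset correlation, the medians were 0.12, 0.00312 and 0.07, and 0 members of any of the 3 lists passed over the list alone, as without MI replicate 2. Without Sham replicate 1 the interferon and complement lists had 0.056 (median 0.25) and 0.307, and 1 complement gene was higher and 1 lower over the list alone. There were 4 higher interferon and 2 higher complement genes without Sham replicate 2, and the complement median was 0.58. The macrophage median was 0.59 without Sham replicate 1 and 0.61 without MI replicate 2. In limma on FPKM with a pseudocount of 0.1 the interferon, macrophage and complement medians were 0.66, 0.61 and 0.60. The macrophage list had 0.846 without Sham replicate 2, and without mitochondrial transcripts the macrophage and complement lists had 0.0872 and 0.0951. T and NK cell (0.8), B and plasma cell (0.474), antigen presentation (0.248) and inflammasome and NF-kappaB (0.945) lists were not called. In the last, Hmgb1, named after its value was seen, was lower adjusted over the list alone (-1.48 ± 0.13). Without either MI library 0 members of that list passed, without Sham replicate 1 there were 1 higher and 2 lower, and without Sham replicate 2 there were 1 higher and 1 lower. Without Sham replicate 2, which held the highest level of 12 of 18 B and plasma cell markers, the T and NK cell and antigen presentation lists were called higher (adjusted p = 0.0108 and 0.00152). The B and plasma cell list was called lower without Sham replicate 1 (4.89e-06) and higher without Sham replicate 2 (0.00691).

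Immediate early genes were lower in MI (median -0.68; camera adjusted p = 2.17e-05, and adjusted p = 0.603 with an estimated correlation), with 2 of 24 lower adjusted over the list alone (5 in DESeq2). The median was -0.22 in limma on log2(FPKM + 1) and -0.17 with a pseudocount of 0.1. The 2 were Junb (-1.18 ± 0.17) and Zfp36 (-0.93 ± 0.17), named after their values were seen, while the abundant Ccn1 and Jund had 0.57 ± 0.26 and 0.06 ± 0.34. Without Sham replicate 2 the list was not called (0.295, median -0.12), and without either MI library 0 members passed over the list alone. Without Sham replicate 1 the lower members numbered 12 (median -1.04), and without Sham replicate 2 there were 1 higher and 1 lower. Cell cycle genes had a median of 0.55 (adjusted p = 7.3e-04; adjusted p = 0.677 with an estimated correlation) with 0 of 36 passing over the list alone in edgeR (6 higher at an unadjusted p, and 0 in DESeq2). The median was 0.26 in limma on log2(FPKM + 1) and 0.06 after quantile normalization. Pcna and Ccnd1 had -0.12 ± 0.13 and -0.02 ± 0.21. That call ended without Sham replicate 1 (0.0957, median 0.36) and without MI replicate 1 (0.258, median 0.20). Antioxidant defence genes had a median of -0.15 (adjusted p = 0.03; adjusted p = 0.603 with an estimated correlation) with 0 of 31 passing over the list alone in edgeR (1 lower without either Sham library). At an unadjusted p 1 was higher and 4 lower, and DESeq2 called 2 lower. The glutathione peroxidases Gpx4 and Gpx3 had -0.17 ± 0.15 and 0.45 ± 0.20. That call ended without Sham replicate 1 (0.207, median -0.04), MI replicate 1 (0.0834, median -0.04) or MI replicate 2 (0.0697), and the median was 0.09 in limma on FPKM. The antioxidant call also ended without mitochondrial transcripts (0.0911, median -0.0185) and after quantile normalization (0.382, median -0.0263). A mean FPKM of at least 5 (0.333) or 1 (0.0798) ended it too. Oxidant production genes were not called (0.112). Nox4, an NADPH oxidase, was higher (2.25 ± 0.27) and the monoamine oxidase Maob lower (-0.68 ± 0.13) adjusted over the list alone, both named after their values were seen. Without either MI library 0 members of that list passed, without Sham replicate 1 there were 3 higher and 1 lower, and without Sham replicate 2 there was 1 higher.

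Apart from the atrial and adipocyte lists, the remaining lists were not called. Endothelial markers (median 0.26) had an adjusted p of 0.0661, and 1.34e-05 to 0.224 over 20 settings, of which 10 called the list higher. Egfl7 and Tcf15 were higher (0.81 ± 0.12 and 1.21 ± 0.18) and the adhesion molecule Selp lower (-3.62 ± 0.47) adjusted over the list alone. Renin-angiotensin, natriuretic and adrenergic genes (0.7; median 0.04, mean -0.12) had 3 higher, Ace, Edn3 and Grk5 (0.97 ± 0.16, 2.07 ± 0.44 and 0.64 ± 0.16), and 2 lower, Agt and Adra1b (-0.99 ± 0.20). In the Schwann cell and neuron list (0.945; median -0.09, test higher) Pmp22 was higher, in the hypoxia list (0.225) P4ha1 was, and in the skeletal muscle list (0.188) Mylk2, which had no counts in Sham. Apart from Agt and Pmp22, these members were named after their values were seen. Over the list alone, endothelial genes numbered 8 higher and 1 lower without Sham replicate 1, 0 without MI replicate 1, and 1 lower without MI replicate 2. Renin-angiotensin genes numbered 5 higher and 4 lower without Sham replicate 1, 1 higher and 1 lower without Sham replicate 2, and 1 lower without either MI library. Hypoxia genes numbered 5 higher and 1 lower without Sham replicate 1, 3 higher without Sham replicate 2 and 0 without either MI library. The Schwann cell list had 1 higher without any single library, and the skeletal muscle list 2 higher without MI replicate 2 and 0 without any other library. The adjusted p was 0.206 for smooth muscle and pericyte, 0.138 for mesothelial and epicardial, 0.945 for red blood cell, 0.271 for unfolded protein and heat shock, 0.956 for circadian clock, 0.451 for cytosolic ribosomal protein, 0.945 for cell death and 0.345 for sex-linked genes. Without Sham replicate 2 the unfolded protein list was called lower (1.92e-06), and without Sham replicate 1 or MI replicate 1 the mesothelial list was (0.00262 and 0.00021). The red blood cell list was called higher without Sham replicate 1 (0.000389) and lower without Sham replicate 2 (0.000661). The skeletal muscle list was called higher without Sham replicate 2 (0.0397) or MI replicate 2 (3.73e-06). Limma on log2(FPKM + 1) ended the calls of the sarcomere (0.22), macrophage (0.445), complement (0.549), antioxidant (0.164) and cell cycle (0.112) lists. A mean FPKM of at least 5 ended those of the interferon (0.0926), immediate early (0.132) and atrial (0.138) lists.

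Markers of other tissues stood apart in single libraries. All 12 atrial markers were highest in Sham replicate 2, where Myl7, the atrial light chain, reached 1127.51 FPKM against 0.46, 1.20 and 0.41 in Sham replicate 1, MI replicate 1 and MI replicate 2, and Sln, sarcolipin, reached 121.43 against 0, 0.10 and 0. The adipocyte genes Adipoq and Ucp1 were at 16.0 and 15.8 FPKM in Sham replicate 2 and listed at 0 in the other libraries. Camera called the atrial and adipocyte lists lower in MI (median -2.45 and -1.26; adjusted p = 7.63e-05 and 2.14e-05). With an estimated correlation the adjusted p was 0.603 and 0.531. Without Sham replicate 2 neither was called (0.295 with a median of 0.23, and 0.0686 with -0.35). The adipocyte median was -5.99 without Sham replicate 1, -4.63 without MI replicate 1 and -5.02 without MI replicate 2. In each, 1 member was lower adjusted over the list alone (11 without Sham replicate 1, and 0 without either MI library). With all libraries these were Tbx5 in the atrial list and Cidea (-1.17 ± 0.16) in the adipocyte list, named after their values were seen. The atrial genes numbered 2 higher and 2 lower without Sham replicate 2. In limma on log2(FPKM + 1) the atrial median was -1.36, and with a mean FPKM of at least 5 it was -7.38. With a pseudocount of 0.1 the adipocyte median was -1.97. The abundant lipid droplet genes Pnpla2 and Plin4 had -0.48 ± 0.19 and -0.41 ± 0.19. Thymus markers did not stand apart: 5 of 8 were highest in MI replicate 1, but they summed to 1.47 FPKM there and 1.74 in Sham replicate 2. In MI replicate 1, 11 of 12 lung markers and 12 of 15 skeletal muscle markers were at their highest. The surfactant gene Sftpc was at 121.81 FPKM there and listed at 0 elsewhere. Too few lung (4) and thymus (3) markers passed the count filter for a list test. The red blood cell markers summed to 17650 and 6708 FPKM in Sham and 11120 and 13540 in MI. Xist, the X-inactivation transcript, was at 0.02 to 0.06 FPKM and the Y-linked Ddx3y at 5.67 to 6.93 in the 4 libraries. Eif2s3y, also Y-linked, differed by 0.01 ± 0.18 between the groups.

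**Figure D3:**
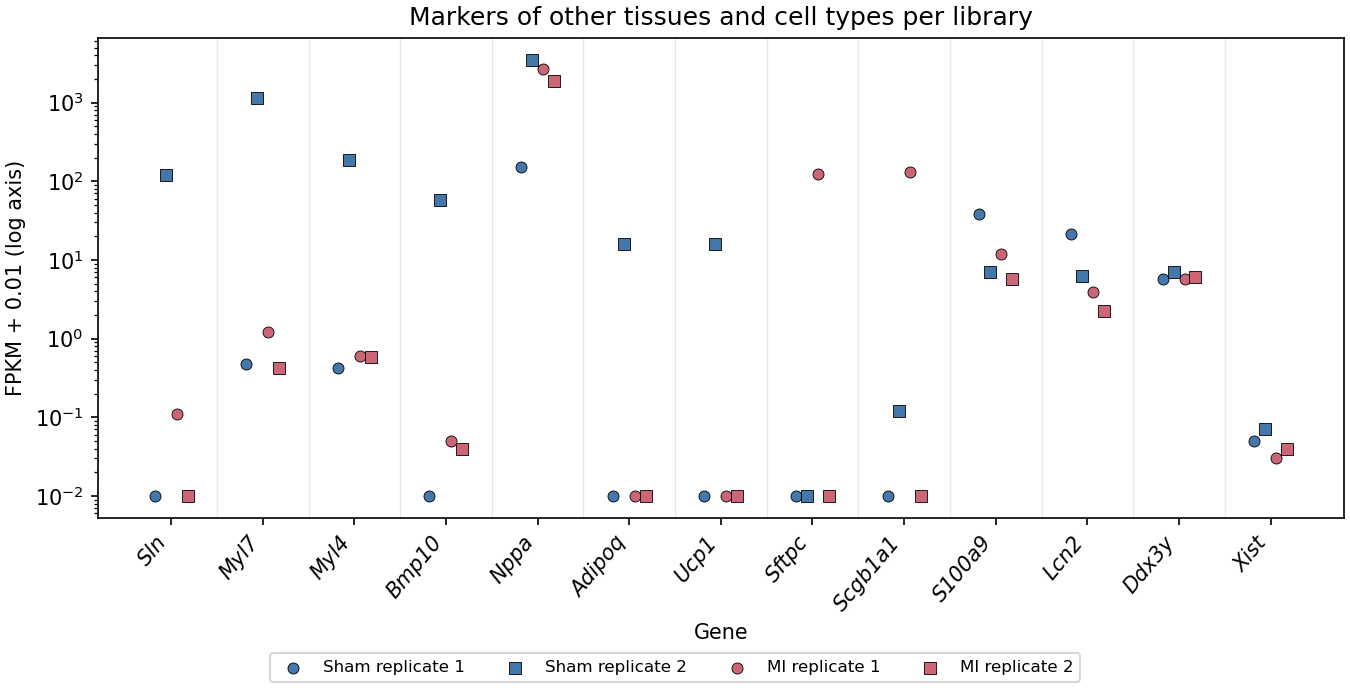
FPKM (log axis, with a small constant added so that 0 can be drawn) of 13 genes typical of other tissues or of sex in each library, with blue for Sham, red for MI, circles for replicate 1 and squares for replicate 2. Sln, Myl7, Myl4, Bmp10, Adipoq and Ucp1 stand out in Sham replicate 2, Sftpc and Scgb1a1 in MI replicate 1, and S100a9 and Lcn2 are highest in Sham replicate 1.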

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

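DESeq2, limma on log2(FPKM + 1), counts divided by 4, the newer quasi-likelihood fit, a mean FPKM of at least 1 and the counts over a list alone without each library were tests chosen after the result was seen. Of 24 called lists, 8 were called in each of 20 settings (collagens, other matrix, collagen processing, activated fibroblast, fatty acid, tricarboxylic acid, respiratory chain and branched-chain amino acid); 16 lost the call or turned in at least 1 (the mitochondrial DNA list after quantile normalization alone), and 0 were called higher or lower with an estimated correlation or fry. Of 128 named genes, 23 changed sign in at least 1 of the settings that tested them; the limma and mean FPKM settings left out those of low FPKM. Depth limits genes near 12 counts per library. Except where shown, the cause was not tested.

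Against 0 genes called, DESeq2 gave 635 (403 higher, 232 lower; 2866 genes had no adjusted p), and an unadjusted p with a 2-fold change 866 (595 and 271). At an unadjusted p, 834 genes were lower; limma gave 207, 202 (pseudocount 0.1), 206 (0.5) and 195 (no trend), and mitochondrial removal 432. A mean FPKM of at least 5, which tests fewer genes, gave 459 higher and 247 lower, and 6 lists lower; quantile normalization gave 834 higher, and 8 lists lower. With the replicate block, 0 genes were called, 552 were lower at an unadjusted p and the complement list lost its call (0.0649), the only list call it changed. The numbers are shared by both groups, but no label pairs them; deviations of same-numbered libraries correlated at -0.0561.

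Leaving out 1 library, which also leaves fewer samples, gave 0 to 14 genes called (0 to 4 higher, 0 to 11 lower), 432 to 1917 higher and 378 to 1209 lower at an unadjusted p, 5 to 14 lists higher, and 40 to 248 terms called, against 183. List medians ranged from -3.24 to 0.23 for atrial, -1.25 to 0.94 for B and plasma cell, -0.67 to 0.82 for red blood cell and 0.00312 to 0.61 for macrophage. Log2 differences ranged from -0.80 to 3.58 for Nppa, -0.76 to 1.10 for Acta1, -1.09 to 1.15 for Timp1, -2.72 to 2.77 for Spp1, -0.34 to 0.57 for Acta2, -0.43 to 1.57 for Ccn2, -0.22 to 0.32 for Gsn, -0.14 to 0.0558 for Hspb7, -2.41 to 0.16 for S100a9, -1.30 to 1.07 for Ccl6, -0.35 to 0.63 for Jund, -0.14 to 0.16 for Eif2s3y, -0.0474 to 0.21 for Ctsd, -0.15 to 0.24 for Ctsb, -0.16 to 0.00472 for Actc1, -0.76 to 0.24 for Ifi27l2a, -0.30 to 0.24 for Ccnd1, -0.39 to 0.13 for Idh2, -10.6 to 0.46 for Myl7, -8.43 to 0.23 for Myl4 and -10.7 to 6.71 for Bmp10.

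The other reversals were small. In limma with pseudocounts 0.1, 0.5 and 1, and without a trend, the differences were 0.239, 0.220, 0.199 and 0.199 for Timp1, 0.143, 0.143, 0.143 and 0.143 for Actc1, 0.169, 0.169, 0.169 and 0.169 for Hspb7, 0.0757, 0.0756, 0.0755 and 0.0755 for Idh2, 0.0832, 0.0702, 0.0559 and 0.0559 for Ccl6, 0.0557, 0.0556, 0.0555 and 0.0555 for Gpx4, 0.104, 0.0997, 0.0952 and 0.0952 for Pcna, and 0.176, 0.170, 0.163 and 0.163 for Ccnd1. After quantile normalization they were 0.0619 for Timp1, 0.223 for Actc1, 0.103 for Hspb7, 0.0081 for Idh2 and 0.00823 for Gpx4, and the list medians 0 for sarcomere, 0 for mitochondrial DNA and 0.0729 for ribosomal protein (called, 0.00229); genes of the same rank get the same value there, so the 0 of the most abundant transcripts, those of mitochondrial DNA, says nothing on their call. Without mitochondrial transcripts they were 0.0563 for Actc1, 0.0890 for Hspb7, 0.00953 for Idh2, 0.0213 for Pcna and 0.126 for Ccnd1. A mean FPKM of at least 5 gave 0.00781 for Actc1, 0.0394 for Hspb7, 0.0723 for Ccnd1 and -0.00306 for the chemokine list, which turned higher in the test; a mean of at least 1 gave 0.0055 for Ccnd1. Timp1 was 0.0173 with the block, and Eif2s3y was -0.00774 with median-of-ratios scaling, -0.00778 in DESeq2 and -0.000532 with counts divided by 4.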

Other observations

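Each of the tests of explanations below was chosen after the result it measures was seen. Beyond the fixed lists, 183 of 2688 annotation terms were called by camera with a preset correlation and 0 with an estimated correlation (adjusted p = 0.98 for each term named here). Among those higher in MI, basement membrane (96 genes) had a median log2 difference of 0.44 with 37 genes higher and 1 lower at an unadjusted p (adjusted p = 4.05e-09). Cartilage and skeletal terms were among them too: negative regulation of chondrocyte differentiation had a median of 1.0 over 17 genes (4.84e-05) and chondrocyte development 0.51 over 19 (7.15e-05). Cartilage condensation had 0.65 over 16 (0.00314; 0.681 without Sham replicate 1 and 0.0889 without MI replicate 1) and skeletal system morphogenesis 0.30 over 40 (0.00403; 0.215 without Sham replicate 1). Wnt-protein binding (26 genes) had a median of 0.51 (1.46e-04; 0.122 without Sham replicate 1), and insulin-like growth factor binding (20 genes) 0.53 (9.58e-04; 0.765 without Sham replicate 1 and 0.0533 without MI replicate 1). Angiogenesis (230 genes) had a median of 0.20 (0.00181) and scavenger receptor activity (38 genes) 0.46 (0.0041), and neither was called without Sham replicate 1 (0.0891 and 0.29) or MI replicate 1 (0.0827 and 0.375).

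Among terms lower in MI, the mitochondrial large ribosomal subunit (60 genes) had a median of -0.20 (0.000529; 0.172 without Sham replicate 1) and brown fat cell differentiation (32 genes) -0.45 (0.00138), including without each library. Sham replicate 2 held fat transcripts. Killing of cells of other organism (23 genes), a host defence term, had a median of -0.94 with 6 genes lower at an unadjusted p (6.7e-05), also without each library.

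Without Sham replicate 2, 5 genes were called, and 3 of them were nearly missing from, or found in, Sham replicate 1 alone: Eif3j2 (0 counts there, 989 and 881 in MI), Adnp (8 counts, 3526 and 3442 in MI) and Gm20716 (3982 counts there and 0 in the other libraries). The genes Spry1 (24 counts) and Alb (0 counts) were low in Sham replicate 2 alone, against 1845 and 1439 counts in Sham replicate 1. No explanation was tested for these values, and the genes were chosen after their values were seen.

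The first pattern is that atrial and fat transcripts were abundant in Sham replicate 2. The levels may come from atrial and fat tissue in that library: 12 of 12 atrial markers had their highest FPKM there, led by Nppa (3515.19), Myl7 (1127.51) and Myl4 (185.53). Nppa was also at 2631.97 and 1855.23 FPKM in MI replicates 1 and 2, so its level alone does not mark atrial tissue. In its collagens Sham replicate 2 was unlike the MI libraries, as 17 of 18 lay below both. That count restates the higher collagen list in MI, and the region taken is not known. It therefore cannot exclude an infarcted heart under a Sham label. Of the 12 atrial markers, 4 reached 1 FPKM in each of the other libraries as well, and 7 belong to another fixed list too. Whether the region taken differed stays open, since the labels give only heart.

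The second pattern is that lung transcripts appeared in MI replicate 1. They may come from lung tissue taken with the heart, as 11 of 12 lung markers were highest there (Scgb1a1 at 130.54 FPKM and Sftpc at 121.81). Of these 12, 0 reached 1 FPKM in each of the other libraries. Lung tissue as the source of the higher collagen list in MI is argued against: without MI replicate 1 the list kept an adjusted p of 3.27e-20 with the preset correlation (1.83e-08 to 5.4e-56 over 20 settings), and its median was 1.58 against 2.14 with all libraries. With an estimated correlation and all libraries the list was not called (0.531). How much of the higher collagen level of MI replicate 1 over MI replicate 2 comes from lung was not tested.

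The third pattern is that the chemokine and immediate early lists were higher in Sham than in MI at day 28, also for the inflammatory genes Ptx3 and Socs3, chosen after their values were seen (-3.80 ± 0.35 and -2.32 ± 0.22). Neutrophil influx into both Sham hearts is only weakly argued against. Of 18 neutrophil and mast cell markers, 6 were higher in Sham replicate 2 than in both MI libraries. That count equals the cut-off for arguing against an influx, which was set after the result was seen. The mast cell genes Cma1, Cpa3, Mcpt4 and Tpsb2 were among the 6 and do not mark neutrophils. The others were Lcn2 and Mmp9, the latter at 0.33 FPKM against 0.30 and 0.10 in MI. In Sham replicate 2 the neutrophil genes S100a8, S100a9, Cxcr2, Csf3r, Mmp8 and Retnlg lay below MI replicate 1. Of these, S100a8, S100a9 and Retnlg lay above MI replicate 2. In Sham replicate 1, 15 markers were higher than in both MI libraries, and an influx there stays open. Atrial and fat tissue of Sham replicate 2 as the source of the chemokine list is argued against by an adjusted p of 1.93e-08 without that library with the preset correlation (1.93e-08 to 0.377 over 20 settings). The call does depend on Sham replicate 1 (0.0994 without it), on MI replicate 2 (0.0552) and on the preset correlation (0.603 with an estimated one). The immediate early list was not called without Sham replicate 2 (0.295). A difference in handling or collection between the groups could also raise such genes. In all, 11 of 24 immediate early genes were lower in both MI libraries than in both Sham libraries. That count restates the pattern and cannot decide between causes. Handling and group cannot be told apart, since no label records the handling, and the infarct itself stays open as a biological explanation.

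The 4 libraries allow 3 splits into pairs, too few for a share under 0.05. The real split, the 1 split that reached that many, gave 2150 genes at an unadjusted p under 0.05, and the highest of the others 516.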
